A study of Laguncularia racemosa with 22 samples.

How the data were processed

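Leaf libraries of *Laguncularia racemosa* seedlings, 22 in all, were analysed from the table of raw counts that the authors deposited, with 1 whole number per gene and library and no normalization visible in the values. Per the submitters' processing notes, FastQC, HISAT2 and featureCounts were used, with no versions or settings given there; FastQC reports read quality, HISAT2 aligns reads and featureCounts counts aligned reads per feature. The gene IDs have the form that Trinity, a de novo transcript assembler, gives, and no assembly, annotation or reference genome was used here. What the reads were aligned to is not given in the sources used here. Reads shared between near-identical assembled genes can be split or lost in such counts: 29.5% of the 54696 IDs share a Trinity cluster, of which there are 45462, with at least 1 other ID, and the 4 genes named in the text are each alone in theirs. The table has 22 value columns, each matched to its sample by letter, time and replicate number, and 0 other value columns.

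Groups were taken from the letter and the time in the sample titles. A replicate 1 of P at 3 h and a replicate 3 of P at 36 h were not analysed here. Before averaging, libraries of each group were compared in pairs by a chi-square per gene, which would be near 1 for sampling noise alone. It ran from 16.1 to 51.6, so no pair differed by sampling noise alone. Each library was counted as a separate replicate, but this value does not show that libraries came from separate plants. The total count of a library was 13743563 to 18462363, and 99.8% to 99.9% of it lay in the genes tested. A gene at 1 CPM therefore rests on 13.7 to 18.5 counts in a library before TMM scaling. A count of 0 over a group was given a floor of 3 counts over that group, and folds against it are lower bounds for counting error only.

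Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with 0 in all libraries numbered 751. The edgeR function filterByExpr, with the 8 groups and a minimum count of 10, left 21694 genes. Libraries were scaled by TMM, negative binomial dispersions were estimated over all 22 libraries together (common biological coefficient of variation 0.26), and the robust quasi-likelihood test was applied to each contrast of the 8 group means. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold, within each contrast. A total of 15 contrasts were tested: 3, 12 and 36 h against 0 h and 36 h against 12 h within each letter, P against Q at each time, and the difference between letters in the change from 0 h to each later time. A further test over the 4 times was made within each letter. Contrasts of 2 libraries against 3 rest on the spread pooled over all groups. CPM values use TMM-scaled library sizes, and log2 CPM for principal components and distances has a prior count of 2. A gene changed at 12 h was counted as moved back when its change from 12 to 36 h was called in the opposite direction. Median log2 changes of called genes were computed with genes at 0 in every library of a group set to their bound. Medians over genes called in both letters and over all genes use the fitted log2 changes without a bound.

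The design, the test, the rule for named genes and the alternatives were fixed before the data were examined, except for those listed as added. By that rule the genes named are the 2 with the largest positive and the 2 with the largest negative log2 change from 0 to 12 h in P, among genes called there, with a mean of at least 5 CPM over all libraries and no overlap between the 3 libraries of each time; 5359 genes met these conditions, 2597 rising and 2762 falling, and 3 libraries against 3 are free of overlap by chance in 10% of genes. Gene lists for cold response, photosynthesis and other functions had been fixed as Arabidopsis gene symbols, and none was tested because the files do not pair IDs with names. No function is therefore assigned to any gene. A test of gene lists with camera was not run for the same reason.

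The alternatives were a minimum change of 2-fold, RLE scaling, no filter, a filter of at least 10 counts in at least 11 libraries, DESeq2 1.42.0, a fit of only the libraries compared, counts thinned to the smallest library total, the replicate number as a block over all libraries or within each letter, and leaving out each library in turn. Alternatives added after seeing the data were library totals without TMM and a fit without the 2 libraries of P at 36 h; summing counts over Trinity clusters was added once the IDs were seen. Overlaps of called genes were set beside the number that independent lists give, and, where comparisons share libraries, beside 5 simulated sets, which had no effect at any time for overlaps with 0 h in common and no change from 12 to 36 h for genes moved back.

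The fit was tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed, 100 of them 4-fold and 100 of them 2-fold. The changed genes were taken from those with a mean of at least 1 CPM in the groups compared. Recovery among genes below that level, or with fewer genes changed, was not measured. For P at 12 h against 0 h, 85% of the 4-fold and 62% of the 2-fold changes were recovered among 21021 genes. For P at 3 h against 0 h the shares were 83% and 44% among 21056 genes, and for P against Q at 36 h 77% and 32% among 21081. For P against Q at 0 h they were 72% and 56% among 21107. Of the genes called, 1.54% to 4.55% had not been changed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.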

Results

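Messenger RNA was measured by sequencing in leaves of *Laguncularia racemosa*, the white mangrove, a tree of tropical tidal shores, in seedlings 8 weeks old. The 22 libraries fell into 8 groups, formed by a letter in the sample titles, P or Q, and by 4 time labels of 0, 3, 12 and 36 h. The treatment labels of P name freezing temperature, and its 36 h label stands for 12 h of cold followed by 24 h of recovery. Those of Q read control at each time. The treatment text that stands with both letters describes seedlings held at 0 °C and returned to 30 °C by day and 28 °C by night, and does not say what the Q seedlings received. Seeds came from 2 places, and the labels do not tie a letter to a place. A difference between P and Q is therefore a difference between everything the letter carries.

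Each group held 3 libraries, except P at 3 h and P at 36 h with 2 each. Total counts ran from 13743563 to 18462363 per library. The table lists 54696 assembled genes, of which 21694 passed the filter on low counts and were tested. The files do not pair the gene IDs with names, so the groups of genes below are defined by their behaviour, and 4 genes are named by ID. No source says that the libraries of a group came from separate plants beyond the extraction of each plant's leaves, and p-values measure the spread between these libraries.

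Time, more than letter, ordered the libraries. The first principal component held 31.1% of the variance and placed all 11 libraries of 0 and 3 h between -82 and -46.4, and all 11 of 12 and 36 h between 37 and 106.5. On the second component, with 15.6%, the 12 h libraries of both letters lay lowest, and the 2 libraries of P at 36 h lay highest, at 96.5 and 118.6, against 8.4 to 33.7 for Q at 36 h. The nearest library by correlation was one of the same time for each of the 22 libraries.

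**Figure D1:**
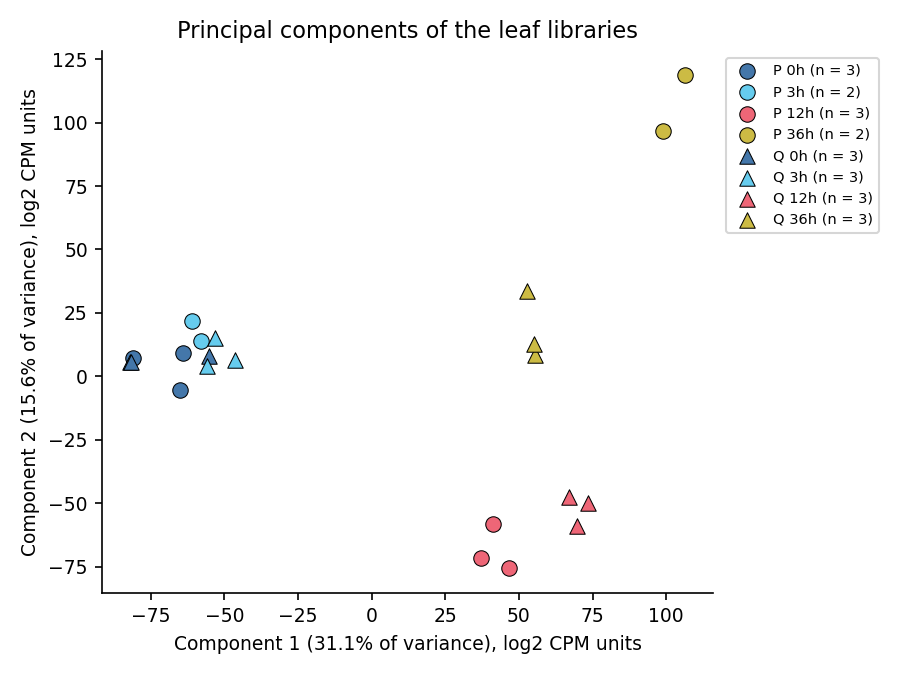
Each point is 1 library, placed by the first 2 principal components of log2 CPM (horizontal and vertical axis, with the percent of variance each holds); colour marks the time label, circles P and triangles Q. The 0 and 3 h libraries lie to the left of 0 and the 12 and 36 h libraries to the right, and the P libraries of 36 h lie apart at 96.5 and 118.6 on the vertical axis.

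The first question was which leaf transcripts changed with time in P, whose labels name freezing temperature. No libraries are documented as untreated over the same hours. Changes in P, here and below, therefore cannot be credited to cold apart from time of day, light or handling. After 12 h, 3368 genes were higher and 3595 lower than at 0 h, together 32.1% of the genes tested. TRINITY_DN10434_c0_g1 rose from 0.594 ± 0.469 CPM (SD, n = 3) to 116 ± 21.5 CPM (SD, n = 3), a log2 change of 7.60 with a standard error of 0.58. TRINITY_DN1106_c1_g1 had no count in any of the 3 libraries at 0 h and 97 to 236 counts at 12 h, at least 204-fold higher against a floor of 3 counts over the group. TRINITY_DN10002_c0_g1 went the other way, from 125 ± 32.3 CPM (SD, n = 3) to 0 counts in all 3 libraries, at least 1700-fold lower. TRINITY_DN12080_c1_g1 fell from 52.8 ± 11.4 CPM (SD, n = 3) to 0.314 ± 0.278 CPM (SD, n = 3), a log2 change of -7.34 with a standard error of 0.65. The adjusted p-values of these 4 genes in edgeR's quasi-likelihood test were 4.5e-08, 0.000193, 2.9e-06 and 2.22e-07 in the order given. Scaling by library totals alone left 36.6% of the called genes higher in place of 48.4%, and moved the median of all genes from -0.04 to -0.17, so the balance of rises and falls depends on the scaling.

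The change had begun by 3 h in P on a smaller scale. There were 818 genes higher and 324 lower than at 0 h, with a median log2 change of 1.26 among the former and -0.91 among the latter. TRINITY_DN1106_c1_g1 was already at 11.3 ± 7.18 CPM (SD, n = 2), with an adjusted p of 0.00226 in edgeR. The other 3 named genes did not pass the test at 3 h: TRINITY_DN10434_c0_g1 stood at 0.949 ± 0.133 CPM, TRINITY_DN10002_c0_g1 at 101 ± 44.2 CPM and TRINITY_DN12080_c1_g1 at 96.2 ± 7.49 CPM (SD, n = 2 each). Of the genes called at 3 h, 453 of the rises and 144 of the falls were called in the same direction at 12 h, where independent lists would share 127 and 53.7; part of the excess may come from the 0 h libraries that both comparisons use. In 5 simulated sets with no effect 0 were shared, which is no reference for lists of this size, since an adjusted test calls few genes where there is no effect. The number of genes called was 1142, and it was 659 without replicate 3 of P at 0 h, 478 without replicate 2 of P at 3 h, 400 without replicate 3 of P at 3 h, 600 with the compared libraries alone and 1826 with DESeq2. The share higher was 71.6%, and 60.8% with library totals alone.

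In Q, whose labels read control, the leaves changed with time as well. At 12 h, 3874 genes were higher and 4320 lower than at 0 h, 37.8% of those tested. TRINITY_DN10434_c0_g1 rose from 0.388 ± 0.261 to 97.6 ± 36.1 CPM, and TRINITY_DN12080_c1_g1 fell from 45.6 ± 11.9 to 0.302 ± 0.357 CPM (SD, n = 3 each), with adjusted p-values of 3.42e-08 and 1.75e-07 in edgeR. TRINITY_DN10002_c0_g1 went from 102 ± 51.2 CPM (SD, n = 3) to 0 counts in all 3 libraries, at least 1620-fold lower. TRINITY_DN1106_c1_g1 rose from 0.0369 ± 0.0319 CPM, 2 counts over 3 libraries, to 7.65 ± 5.99 CPM (SD, n = 3), with an adjusted p of 0.000419 in edgeR. Over the 4 times, 11142 genes changed in Q and 11624 in P.

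At 3 h in Q, 1281 genes were higher and 828 lower than at 0 h. TRINITY_DN1106_c1_g1 had reached 17.8 ± 6.14 CPM (SD, n = 3) and TRINITY_DN10434_c0_g1 2.66 ± 1.11 CPM (SD, n = 3), with adjusted p-values of 0.000697 and 0.0128 in edgeR. Of these genes, 868 of the rises and 459 of the falls were called in the same direction at 12 h, against 228.8 and 164.9 for independent lists; the 0 h libraries are again shared, and the 0 of 5 simulated sets with no effect is again no reference for such lists. The log2 change of TRINITY_DN10434_c0_g1 at 3 h was 2.77 and stayed at 2.37 or more with any library left out, but its adjusted p in edgeR was 0.054 without replicate 1 and 0.0556 without replicate 2 of Q at 0 h (log2 2.67 and 2.41), and 0.0734 without replicate 2 of Q at 3 h (log2 2.37). Without that last library the 2109 genes called became 1321, and with library totals alone 37.8% of the calls were higher in place of 60.7%.

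**Figure D2:**
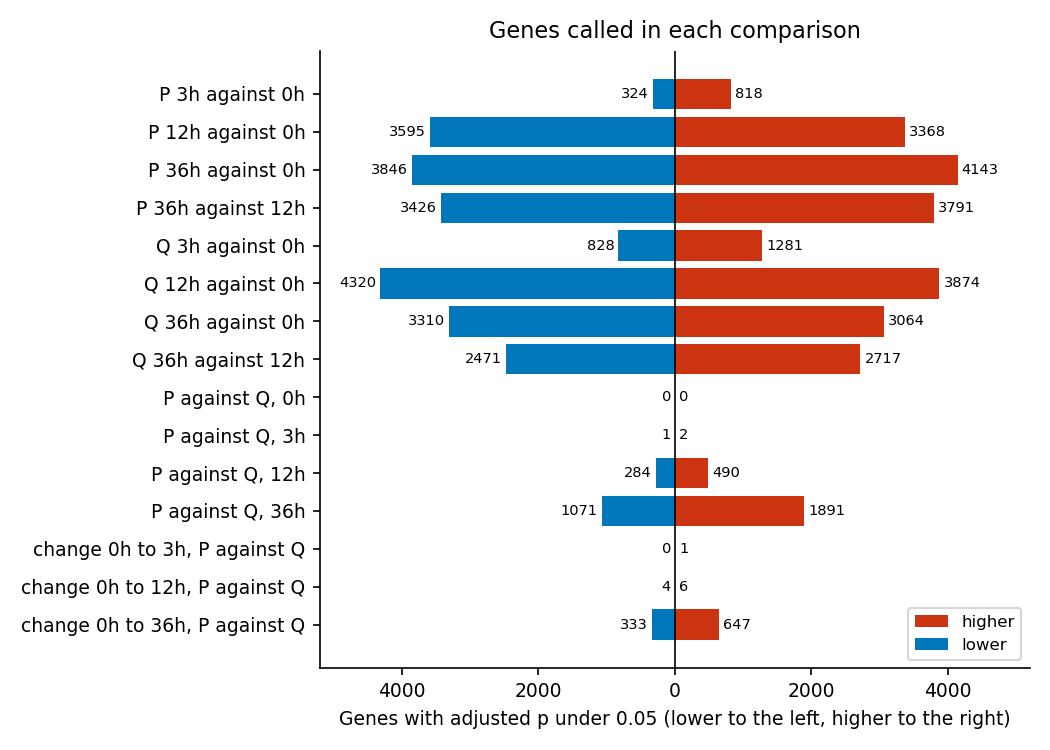
Bars give the number of genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test, higher to the right (red) and lower to the left (blue), for each comparison on the vertical axis. Against 0 h, both letters show 3064 to 4320 genes in each direction at 12 and 36 h, while P against Q goes from 0 genes at 0 h to 1891 higher and 1071 lower at 36 h.

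The changes of the 2 letters largely coincided through 12 h. No library was shared between them, and 2438 of the 3368 genes that rose by 12 h in P also rose in Q, with 2645 of the 3595 that fell, where independent lists would share 601.4 and 715.9. Only 9 genes that rose and 6 that fell in P were called in the opposite direction in Q. Across the 21694 genes, the 12 h change in P correlated with that in Q at a Pearson r of 0.63 and a Spearman rho of 0.66; genes are not independent replicates, and no p is given. The r was 0.79 over genes left by a stricter filter and 0.28 with no filter. At 3 h, 573 rises and 194 falls were shared, against 48.3 and 12.4, with a Pearson r of 0.40 and a Spearman rho of 0.45.

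The next question was what came back in the 24 h after 12 h. In P, 3791 genes rose and 3426 fell between 12 and 36 h. Of the 6963 genes changed at 12 h, 2720 (39.1%) then moved significantly back, 523 moved further the same way, and 3398 (48.8%) were still called against 0 h in the direction of the 12 h change. The latter were 1683 rises and 1715 falls, where independent lists would share 643.2 and 637.3; the 0 h libraries are shared, and part of the excess may come from them. A group of 424 genes passed its starting level and was called on the opposite side of it. These classes overlap: the 424 are part of the 2720 that moved back, and 451 of the 2720 were still called in the 12 h direction. TRINITY_DN10434_c0_g1 was at 53.2 ± 16.8 CPM (SD, n = 2) at 36 h, below its 12 h value by a log2 of 1.13 that did not pass the test (log2 -1.13, standard error 0.46, adjusted p 0.0697 in edgeR), and TRINITY_DN10002_c0_g1 was still at 0 counts in both libraries. TRINITY_DN12080_c1_g1 stood at 0.141 ± 0.199 CPM (SD, n = 2).

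Q moved over the same interval too, with 2717 genes rising and 2471 falling. Of its 8194 genes changed at 12 h, 3084 (37.6%) moved back, 258 moved further, 4309 (52.6%) were still called in the 12 h direction against 0 h, and 101 passed their starting level. Those still called were 2081 rises and 2228 falls, against 547.2 and 659.1 for independent lists, with the 0 h libraries shared as in P. The classes overlap as in P, and 899 of the 3084 genes that moved back were among those still called. TRINITY_DN10434_c0_g1 went from 97.6 ± 36.1 to 35 ± 17.9 CPM (SD, n = 3 each) and TRINITY_DN1106_c1_g1 from 7.65 ± 5.99 to 0.456 ± 0.332 CPM (SD, n = 3 each), with adjusted p-values of 0.0146 and 0.00766 in edgeR. TRINITY_DN10002_c0_g1 remained at 0 counts in all 3 libraries. In both letters the 12 h libraries enter both changes, and part of the genes counted as moved back may come from this. In 5 simulated sets with no change from 12 to 36 h at most 0 genes moved back in P and 1 in Q, which again is no reference for lists of this size. The log2 change of TRINITY_DN10434_c0_g1 was -1.48; it was -1.16 without replicate 3 of Q at 12 h, -1.24 without replicate 1 and -1.36 without replicate 3 of Q at 36 h, and -1.51 with no filter, with adjusted p-values in edgeR of 0.0626, 0.0615, 0.0612 and 0.0602 that no longer passed.

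Against 0 h, the 36 h leaves of P differed in 4143 genes higher and 3846 lower, and those of Q in 3064 higher and 3310 lower. The median log2 change of the genes called higher was 1.78 in P and 1.26 in Q, over different lists, and 1856 genes in P and 929 in Q were higher by at least 4-fold. Over the 2075 genes called higher in both letters the medians were 1.60 in P and 1.49 in Q, and the change was larger in P for 57.5%. The letters shared 2075 rises and 2290 falls against 0 h, where independent lists would share 585.1 and 586.8. Between 12 and 36 h they shared 1168 rises and 1273 falls, against 474.8 and 390.2, and 202 genes that rose in P fell in Q. The Pearson r across genes was 0.24 for the change from 12 to 36 h and the Spearman rho 0.35, against 0.60 and 0.61 for the change from 0 to 36 h. Without replicate 2 of P at 36 h the genes called against 0 h went from 7989 to 5257, those called against 12 h from 7217 to 4267, and those that moved back from 2720 to 1793. With library totals alone the share rising from 12 to 36 h was 70% in place of 52.5% in P and 63.2% in place of 52.4% in Q.

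**Figure D3:**
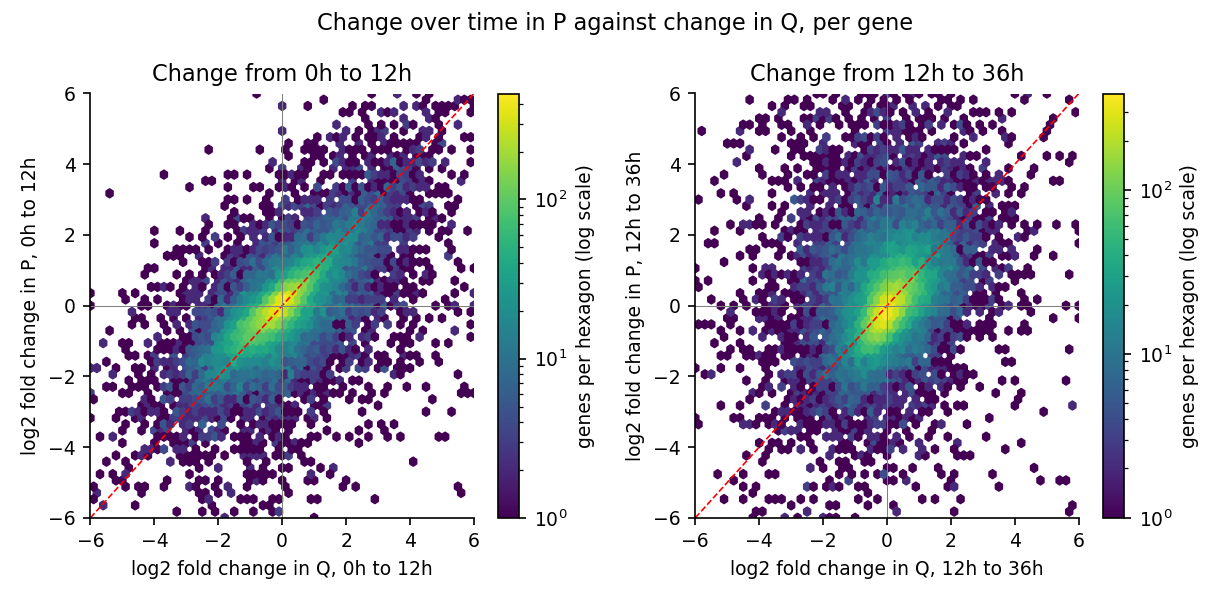
Hexagons count genes (colour, log scale) by their log2 fold change in Q (horizontal axis) and in P (vertical axis), from 0 to 12 h on the left and from 12 to 36 h on the right; the dashed line marks equal change, and 213 genes on the left and 403 on the right lie outside the axes. The genes lie closer to the line on the left (Pearson r 0.63) than on the right (Pearson r 0.24).

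P and Q were then compared directly at each time. At 0 h no gene passed edgeR's test. An unadjusted p under 0.05 was reached by 1345 genes. With no difference at all, a share of 0.05 of the 21694 genes tested would reach it, here and at 3 h. DESeq2 called 18 genes, and each of the 4 named genes had an adjusted p of 0.939 or more in edgeR. At 3 h, 3 genes passed. In the clearest of them P stood at 130 ± 36.3 CPM (SD, n = 2) and Q at 26 ± 3.24 CPM (SD, n = 3), from 27.9 ± 8.08 and 28.9 ± 1.42 CPM (SD, n = 3 each) at 0 h. The other 2 had log2 differences of 1.09 (standard error 0.17) and -3.83 (standard error 0.59), both with an adjusted p of 0.0233 in edgeR. These 3 genes were singled out after their values were seen, and their IDs carry no name and are not printed. DESeq2 called 27 genes at 3 h, 1237 had an unadjusted p under 0.05, and 1 gene was called without replicate 2 of P at 3 h, replicate 1 of Q at 3 h or replicate 2 of Q at 3 h, while the compared libraries alone gave 0.

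At 12 h, 490 genes were higher and 284 lower in P than in Q. The median log2 difference was 0.63 among the former and -1.64 among the latter, and of the genes that also differed by at least 2-fold 55 were higher and 193 lower in P. Of the 490, 134 had risen and 159 fallen in P from 0 to 12 h, and 35 had risen and 333 fallen in Q. Of the 284, 28 had risen and 93 fallen in P, and 156 had risen and 16 fallen in Q. The 12 h libraries enter both the choice of these genes and these changes, so part of these splits follows from the choice. None of the 4 named genes differed, with adjusted p-values of 0.738 or more in edgeR. The 774 calls depended on each library: leaving out replicate 1, 2 or 3 of P at 12 h gave 1453, 99 or 8, and leaving out replicate 1, 2 or 3 of Q at 12 h gave 109, 41 or 472. The compared libraries alone gave 0 genes and DESeq2 1511, and with library totals alone 40% of the calls were higher in P in place of 63.3%.

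At 36 h the letters parted, with 1891 genes higher and 1071 lower in P. The median log2 difference was 1.77 among the genes higher in P and -0.78 among those lower. Of the 1891, 1492 had risen in P from 12 to 36 h, while in Q 144 had risen and 409 had fallen. Of the 1071, 707 had fallen in P and 280 had risen in Q. The 36 h libraries enter both the choice of these genes and these changes, so part of these splits follows from the choice. Over all genes tested, 3791 rose and 3426 fell in P from 12 to 36 h, and 2717 rose and 2471 fell in Q. TRINITY_DN1106_c1_g1 was at 14.3 ± 17.5 CPM in P, from 35 and 488 counts in its 2 libraries, and at 0.456 ± 0.332 CPM in Q (SD, n = 3), a log2 difference of 4.92 with an adjusted p of 0.0049 in edgeR. Without replicate 2 of P the difference fell to a log2 of 2.09 (adjusted p 0.245), while with the compared libraries alone it was 4.95 and only the p moved past the threshold (adjusted p 0.0605). Without replicate 2 of P at 36 h, 971 genes were called in place of 2962.

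Distances between libraries followed the same course. Per gene, the mean distance in log2 CPM between a P and a Q library was 0.81 at 0 h, equal to the 0.81 within letters. It was 0.79 against 0.73 at 3 h, 0.96 against 0.83 at 12 h and 1.19 against 0.75 at 36 h. In a one-sided exact permutation test of the excess the p was 0.4 at 0 h and 0.1 at each later time, the smallest that the 10 possible splits allow.

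The last comparison was whether the change since 0 h differed between the letters, tested as an interaction. From 0 to 3 h it differed for 1 gene, the one at 130 CPM in P above (log2 2.38, standard error 0.27, adjusted p 0.00065 in edgeR). An unadjusted p under 0.05 was reached by 1196 genes, where no difference at all would give a share of 0.05 of the 21694 tested. The compared libraries alone gave 0 genes, no filter 4 and DESeq2 23, and 2 were called without replicate 1 of P at 0 h. From 0 to 12 h it differed for 10 genes, 6 higher and 4 lower in P relative to Q, all 10 among those called between the letters at 12 h. Those 10 became 0 without replicate 2 or 3 of P at 0 h, replicate 3 of P at 12 h, replicate 1 or 3 of Q at 0 h, or replicate 1 or 2 of Q at 12 h, and 3 without replicate 2 of P at 12 h. They became 31 without replicate 3 of Q at 12 h, 204 without replicate 1 of P at 0 h, 230 without replicate 2 of Q at 0 h and 388 without replicate 1 of P at 12 h. The compared libraries alone gave 0, RLE scaling 3, a stricter filter 40, no filter 232 and DESeq2 729. From 0 to 36 h the change differed for 980 genes, 647 with the higher and 333 with the lower change in P. Of the 647, 559 rose in P since 0 h, with a median log2 change of 2.09 in P and -0.12 in Q; 121 rose and 135 fell in Q. None of the 4 named genes passed these tests, with adjusted p-values of 0.409 or more in edgeR. This is no evidence of equal change where counts of 0 leave the difference poorly determined. TRINITY_DN10002_c0_g1 was at 0 counts in both letters at 12 and 36 h, so its tests there (standard errors 863.42 and 858.51) could not pass. TRINITY_DN1106_c1_g1 had no count in P at 0 h, and its change to 36 h differed by a log2 of 7.45 with a standard error of 4.36. Among the 980, 924 were also called between P and Q at 36 h in the same direction. The 36 h libraries of both letters enter both tests, so much of this overlap is built in and it lends no separate support. The same holds for the overlap of the 10 genes at 12 h and for the changes of the 647 genes within each letter. Leaving out replicate 2 of P at 36 h gave 303 genes, replicate 3 of Q at 0 h 630, replicate 2 of Q at 36 h 640 and replicate 3 of Q at 36 h 535; DESeq2 gave 1631, and library totals alone left 80.3% with the higher change in P in place of 66%.

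**Figure D4:**
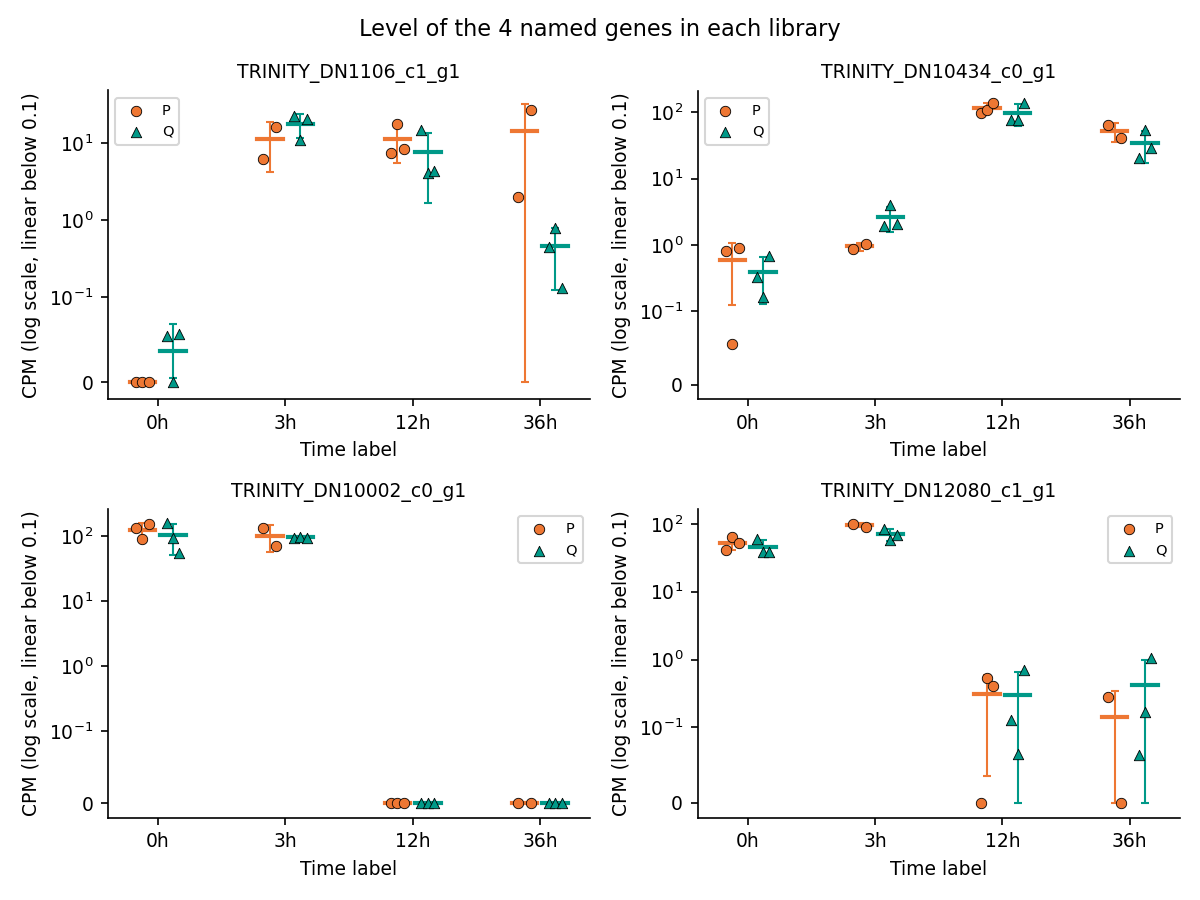
Points are libraries, at their CPM (vertical axis, logarithmic above 0.1 and linear below) by time label (horizontal axis), with P as circles and Q as triangles; bars are group means and whiskers 1 SD, ended at 0 where they would pass it. TRINITY_DN10002_c0_g1 is at 0 in each library of 12 and 36 h in both letters, and TRINITY_DN1106_c1_g1 at 36 h is at 14.3 CPM in P and 0.456 CPM in Q on average.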

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

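Of the tests in this part, the look at which assignments called many genes was chosen only after the result was seen. The change since 0 h differed between P and Q, by a test of the difference itself, for 1 gene at 3 h, 10 genes at 12 h and 980 genes at 36 h. The 1 gene at 3 h stood at 130 ± 36.3 CPM (SD, n = 2) in P and 26 ± 3.24 CPM (SD, n = 3) in Q. For the 10 genes at 12 h chance was not excluded: of 100 drawn ways to assign the letters within 0 h and within 12 h, 7 gave 10 genes or more, the real one included, and the highest other gave 1089. That is far more than the real assignment and points to a structure of the libraries. Of the 6 other assignments with as many genes, 5 kept the 12 h libraries grouped by letter, as labelled or with all letters exchanged. They differed from the real assignment in how the 0 h letters stood against those of 12 h. Whether the 0 h letters were mixed or all exchanged was not recorded. Assignments with the 12 h libraries so grouped gave a median of 10.5 genes and the other 89 a median of 0. A candidate explanation, which was not tested, is that the 12 h libraries differed by letter while the 0 h libraries differed among themselves along other lines. No such count was made for the differences at 3 and 36 h, where P has 2 libraries.

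At 36 h the pattern was 1891 genes higher in P than in Q, 1492 of which had risen in P after 12 h. The P libraries of 36 h enter both numbers, so part of the 1492 follows from the choice of genes. Of the 1891 genes, 70.3% were at 1 CPM or more in every Q library of 36 h. This argues against RNA of an organism found only in the 2 P libraries as the whole cause. An organism in both letters, but more abundant in P, would give the same value, so it is not decided here. For the other 562 genes this value does not decide either. Their larger differences (median log2 4.46 against 1.17 for the rest) follow in part from choosing them by a low level in Q. A difference in depth is argued against as well, since 2033 genes were higher in P with counts thinned to equal totals. An outlying library among the 2 stays open: 1552 genes were higher without replicate 1 and 786 without replicate 2, between the bounds set for either reading. A biological difference between the letters, in seed source or in treatment, is a hypothesis that stays open and was not tested. The labels of P name freezing temperature and those of Q read control, but what the Q seedlings received is not described. No label ties a letter to a seed place.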

How the results depend on the processing

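Library totals without TMM, the fit without the 2 libraries of P at 36 h and counts summed by Trinity cluster were chosen after seeing the data; these and thinned counts kept each count within 1.5 times its value. Library totals moved the median log2 change of all genes from 0.06 to 0.26 for P at 36 h against 12 h, from -0.02 to -0.13 for Q at 3 h, from -0.02 to -0.14 for Q at 12 h and from -0.01 to 0.10 for the interaction at 36 h. The cause of the following changes was not tested, except that fewer genes or libraries enter by construction where a threshold, a filter or fewer libraries are named. With a minimum change of 2-fold, P gave 665 genes at 3 h, 3561 at 12 h and 4646 at 36 h against 0 h and 3781 at 36 h against 12 h; Q gave 941, 4597, 3346 and 2217; P against Q gave 248 at 12 h (55 higher and 193 lower in P) and 1713 at 36 h. With only the libraries compared, P at 3 h gave 600 genes, P against Q 0 at 3 h and 0 at 12 h, and the interaction 0 at 3 h and 0 at 12 h. DESeq2 gave 1826 genes for P at 3 h, 18, 27 and 1511 for P against Q at 0, 3 and 12 h, and 23, 729 and 1631 for the interaction at 3, 12 and 36 h. With no filter, P against Q gave 11 genes at 0 h and 19 at 3 h, the interaction 4 at 3 h and 232 at 12 h, and the correlation of the 12 h changes was 0.28; a stricter filter gave 40 genes for the interaction at 12 h and a correlation of 0.79, and RLE scaling 3 genes (1 higher, 2 lower) for that interaction. Replicate numbers did not pair the libraries: deviations from group means correlated at -0.003 for the same and 0.001 for other numbers on average, and 8 of 22 libraries correlated best with their own number. With the replicate block, P against Q gave 1 gene at 3 h, and the interaction 3 at 3 h and 1 at 12 h; with the block within each letter, P against Q gave 3 genes at 12 h and 1414 at 36 h, and the interaction 6 at 12 h. The block moved no other count by over 1.5 times. Leaving out each library in turn gave 400 to 1092 genes for P at 3 h, 5257 to 7372 for P at 36 h, 4267 to 6662 for P at 36 h against 12 h, 1793 to 2498 moved back in P, and 1321 to 1848 for Q at 3 h. It gave 0 to 5, 1 to 3, 8 to 1453 and 971 to 2266 genes for P against Q at 0, 3, 12 and 36 h, and 1 to 2, 0 to 388 and 303 to 935 for the interaction at 3, 12 and 36 h; where this leaves 1 library in a group, it is assumed to vary like the others. Other counts stayed within 1.5 times their values. Of 422 values of the 4 named genes under the alternatives, 410 kept their side of the threshold, 10 were no longer called, 2 became called and 0 changed direction among those called in either fit. The 410 include 13, 15 and 13 values of TRINITY_DN10002_c0_g1 that could not change, since both groups had 0 counts. In that order, they are for 36 h against 12 h in P and in Q and for P against Q at 36 h. With the block within each letter, TRINITY_DN1106_c1_g1 was not called between P and Q at 36 h (log2 2.62 in place of 4.92, adjusted p 0.217 in edgeR, with 3.53e-05 to 0.245 over the alternatives). Thinning to 13743563 counts per library moved no count by over 1.5 times, but library totals differ too little for this to show what deeper libraries would call.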

Other observations

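The tests of a daily rhythm and of low temperature in Q, the scores of shared genes and the presence patterns were chosen only after the results were seen. One assembled gene was present or absent by time alone: TRINITY_DN10002_c0_g1 had 980 to 2877 counts in each of the 11 libraries of 0 and 3 h and 0 counts in each of the 11 libraries of 12 and 36 h, in both letters. It was the only gene of the table with at least 50 counts in the former and at most 1 in the latter. No gene showed such a pattern between the 10 P and the 12 Q libraries in either direction, while 6 genes had at least 50 counts in both P libraries of 36 h and at most 1 in the other 20. A wider set of 177 genes had at least 10 counts in both of those libraries and stayed under 0.5 CPM in the rest; they took 0.0458% and 0.0732% of the counts in replicates 1 and 2.

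The size of the shared 12 h response was compared between the letters. For the 2438 genes that rose in both, the mean change per library from the letter's own 0 h mean was 1.5 ± 0.02 log2 units in P and 1.57 ± 0.05 in Q (SD, n = 3 each). For the 2645 genes that fell in both it was -1.22 ± 0.03 in P and -1.39 ± 0.02 in Q (SD, n = 3 each). The 0 h libraries themselves spread by an SD of 0.07 in P and 0.12 in Q over the first set and of 0.06 and 0.08 over the second, which a permutation of the 12 h or 36 h libraries alone leaves out, so no p is given for a difference between the letters. At 36 h the genes of the first set stood at 1.17 ± 0.01 in P (SD, n = 2) and 1.15 ± 0.09 in Q (SD, n = 3), and those of the second at -0.86 ± 0.03 and -0.84 ± 0.07. The genes were picked for their 12 h change, which inflates the 12 h values against those of 36 h. At 3 h they stood at 0.39 ± 0.02 in P (SD, n = 2) and 0.56 ± 0.08 in Q (SD, n = 3) for the rising set and at -0.09 ± 0.03 and -0.26 ± 0.08 for the falling set.

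In Q, whose labels read control, 11142 genes changed with time. A rhythm that repeats each day is argued against as the whole cause, since 5188 genes were called between 12 and 36 h, which are 24 h apart. A difference in depth is argued against too, since 8090 genes were called at 12 h with thinned counts, against 8194. Low temperature applied to Q as to P is a candidate explanation; the 12 h changes of the letters correlated at 0.63 across genes, a value that handling, light or time common to both could also give, so these cannot be told apart without libraries documented as untreated over the same hours. Of 100 drawn ways to assign the 12 libraries of Q to the 4 times, only the real one gave as many as 11142 genes. The highest other gave 8998. This argues against chance without excluding it, since 1 of 100 is the smallest share that these draws allow. The other ways put libraries of different times together. Where the times differ, this raises the spread within groups and lowers their counts, so the gap between 11142 and 8998 lends no support of its own.

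For comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. The real and the highest other numbers of genes were 6963 and 3 for P at 12 h against 0 h, 2109 and 0 for Q at 3 h, 8194 and 1 for Q at 12 h, 6374 and 0 for Q at 36 h, 5188 and 1 for Q at 36 h against 12 h, and 774 and 12 for P against Q at 12 h. In each of these 1 of the 10 splits, the real one, gave as many genes. The other splits put libraries of both groups together. Where the groups differ, this raises the spread within them and lowers the number of calls, so these low numbers lend no support. For P against Q at 0 h the real number was 0 and the highest other 35, so all 10 splits gave as many.

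No gene was called between P and Q at 0 h by edgeR, with 1345 at an unadjusted p under 0.05 and 18 by DESeq2. With no difference at all, a share of 0.05 of the 21694 genes tested would have an unadjusted p under 0.05. Too few libraries or reads may hide differences. Among genes at a mean of at least 1 CPM, the fit recovered 72% of simulated 4-fold and 56% of simulated 2-fold changes in this comparison. These shares lie between the bounds set for either reading, so some differences of these sizes could have been missed. They hold for 200 changed genes. Were fewer genes different, the adjusted threshold would be stricter and the shares lower, by an amount that was not measured. Genes below that level were not covered. Whether the letters had different starting states stays open.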
